A study of Mus musculus with 6 samples.

How the data were processed

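Gene expression was compared between 3 control libraries and 3 libraries labelled mutant, all from the transition zone of the mouse lens at E14.5. Per the labels' protocols, embryos of mixed strain background were frozen in embedding medium, and RNA was reverse transcribed and amplified with an ultra-low input kit of the SMART-seq type before tagmentation and Illumina sequencing. Such a kit amplifies full-length cDNA by PCR without molecular identifiers and does not mark strand. Overlapping and antisense genes may therefore share counts, depending on the read counter. Intervals cover counting error only. Groups and replicate numbers were taken from the sample titles and genotypes in the labels.

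The submitters' processing notes name bcl2fastq 1.8.4, TopHat, Cufflinks, DESeq and the genome build mm9, without roles. The read counter, the annotation, the strand setting and any filters are not given in the sources used here. The authors deposited raw counts per gene symbol for each library, as whole numbers that are not normalized, and the same counts in a table of the whole series. Both sources held identical counts for all 23420 genes, with 0 differing. The authors also deposited a table of their own comparison, whose mean of normalized counts is a signal averaged over libraries. That deposited table gives log2 fold changes with their standard errors, a test score, p-values and adjusted p-values. The sign of its log2 fold changes was read against the deposited counts, and positive values stand for higher expression in the mutant libraries. Genes are named by symbol only, as in the files. The reference annotation used here is of the assembly GRCm38.p6, another build than the authors', so it served only for the order of neighbouring genes and no coordinates are given.

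Library totals lay between 13364742 and 17301168 counts. A count of 0 in the shallowest library allows up to 0.224 CPM (3 counts). Replicates within a group differed by far more than sampling noise (chi-square per degree of freedom between 30.2 and 149), so no library was counted as a copy of another. Mutant library 1 had 711 counts of Xist and 2 of Ddx3y, while each of the other 5 libraries had between 521 and 890 counts of Ddx3y, so this library differs from the others in the sex of its tissue. The fits that leave out mutant library 1 also leave out this difference.

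Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 12257 genes, library sizes were scaled by TMM, and groups were compared by the robust quasi-likelihood F test without covariates. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and 0.05 was the threshold. Normalized CPM values use the TMM factors, and standard errors of log2 fold changes were derived from the F statistic. Where 1 group had a single count, the ratio of summed counts is given with its exact 95% interval. Gene lists were fixed before the data were examined, 31 in number with 570 entries, of which 1 was not found by symbol. Of these, 29 were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 29 lists. The remaining lists were the targeted genes and the sex-linked genes. None of the 29 lists was called by camera with an estimated correlation, where 2 had an unadjusted p under 0.05, against 12 at the preset correlation and 2 by fry. The share of counts from 16 crystallin genes was compared by an exact permutation test.

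Genes named in the text follow a rule fixed before the data were examined. It took Etv1, Etv4 and Etv5; the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean of at least 5 CPM in either group and no overlap between groups; and up to 4 members of lowest p from each list described. Predicted genes, antisense, small RNA and pseudogene names were skipped in the ranking and counted only, and 19 called genes were of this kind. Genes outside this rule, other than those used only to check the samples, are stated to have been chosen after their values were seen.

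The procedure was tested on simulated counts with the means and library sizes of this comparison of mutant with control libraries. Of genes changed by a log2 fold change of 1 in size, 29.9% of 97 were recovered, and of those changed by 2, 83% of 100, among 12063 tested genes. There were 8 false calls, 6.67% of all calls, and 0 calls when no gene was changed. Each gene was drawn independently of the others, so variation that many genes share, such as that in crystallin share, was left out. These rates may therefore not hold for the real libraries.

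Alternatives fixed before the data were examined were DESeq2 size factors, normalization without crystallin genes, no filter, a stricter filter of 5 CPM in 3 libraries, the replicate number as a block, DESeq2 1.42.0 and limma voom with quality weights as other tests, other thresholds, and leaving out each library in turn. The crystallin share as a covariate, and leaving out the library of highest crystallin share from each group, were added after seeing the data.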

Results

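Gene expression was measured by RNA sequencing in the transition zone of the mouse lens at E14.5. The transition zone is the band of the lens in which epithelial cells leave the cell cycle and begin to elongate into fibre cells. The 6 libraries fall into 2 groups of 3. Control libraries came from embryos with the Le-Cre transgene, which makes Cre recombinase in the surface ectoderm that forms the lens. Libraries labelled mutant came from embryos that carried Le-Cre together with null alleles of Etv4 and floxed alleles of Etv5 and Etv1. These genes encode the Pea3 family of ETS transcription factors, which act downstream of fibroblast growth factor (FGF) signalling. The question was which genes of the transition zone depend on the Pea3 factors. Summed gene counts were 16661203, 17092433 and 16162956 in control libraries 1, 2 and 3, and 17301168, 13364742 and 16443805 in mutant libraries 1, 2 and 3. One count therefore stood for between 0.0578 and 0.0748 CPM (counts scaled to library size). The labels do not say whether each library came from a separate embryo, so p-values measure the spread between these libraries.

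In the libraries labelled mutant, Etv1 fell, while Etv5 was lower by a similar margin without passing the threshold and Etv4 was not lower. The early growth factor response genes Egr1, Fos and Junb rose, whereas the FGF signalling antagonist Spry2 and the receptor gene Fgfr1 fell. Fibre genes Bfsp2, Gata3, Grifin and Cdkn1c fell, and so did the Notch ligand gene Jag1 and the genes Mtor and Tsc2 of the mTOR pathway, while Maml2 and Rragd of these pathways rose and neither list was called. All 28 tested genes of S phase had positive log2 fold changes, although 1 of them passed the threshold by itself in edgeR. These genes moved nearly together, and mutant library 2 lay at the level of control libraries 2 and 3. Bfsp2, Mtor and Tsc2 each lay near another called gene in gene order. Inherited strain segments stay a candidate explanation for part of the called genes.

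Etv1 averaged 57.4 CPM ± 12.7 (SD, n = 3) in control libraries and 26.5 CPM ± 4.25 (SD, n = 3) in mutant libraries. Its log2 fold change was -1.11 ± 0.21 (SE; edgeR adjusted p = 0.0319). Etv5 averaged 196.8 CPM ± 42.3 (SD, n = 3) and 103.5 CPM ± 18.0 (SD, n = 3), a log2 fold change of -0.93 ± 0.19 (SE; edgeR adjusted p = 0.0503). Etv4 stood at 2.75 CPM ± 0.562 (SD, n = 3) in control and 4.28 CPM ± 0.610 (SD, n = 3) in mutant libraries, and its log2 fold change of 0.64 ± 0.36 did not pass (SE; edgeR adjusted p = 0.427). The values of the groups did not overlap for any of the 3 genes. Of the list of 3 genes, 1 passed over all genes tested and 2 when adjusted over the list alone. Counts per gene include exons that a deletion may leave in place, and the positions of the deleted parts are not given in the sources used here. The counts of Etv1, Etv4 and Etv5 therefore do not by themselves check the labels. The Etv1 call was lost without control library 2 or 3 or mutant library 1 or 3, where its log2 fold change lay between -1.18 and -0.94.

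**Figure D1:**
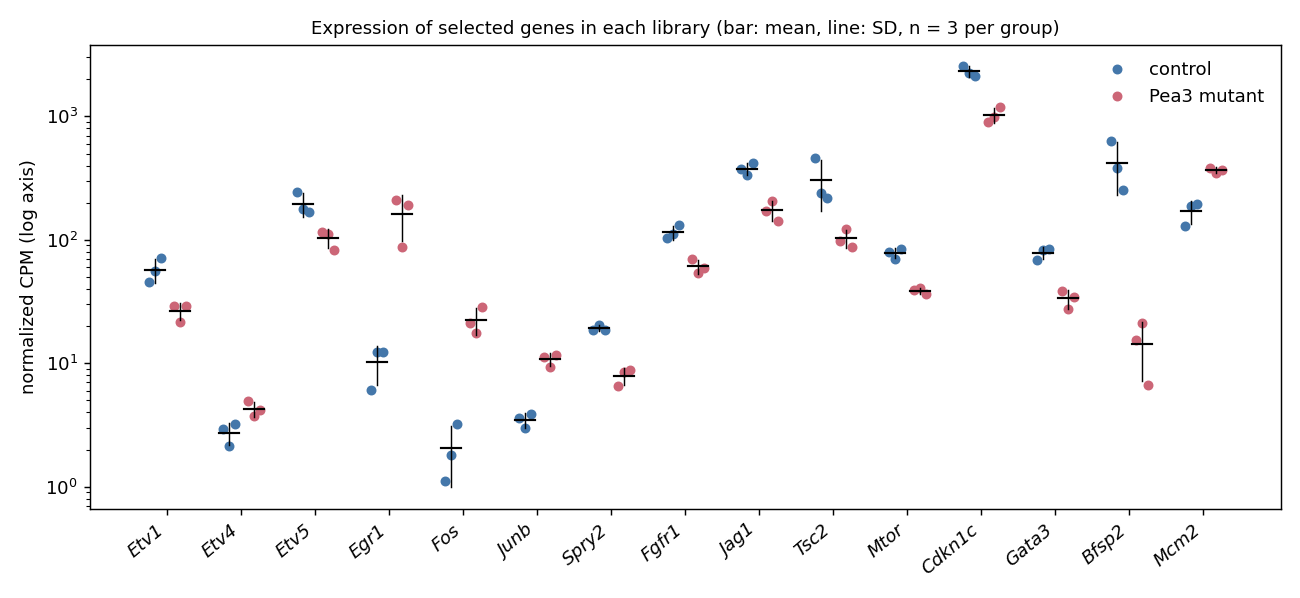
Normalized CPM on a log axis for 15 genes in each of the 6 libraries, with control libraries in blue and libraries labelled mutant in red. Horizontal bars are group means and vertical lines the SD (n = 3); Egr1, Fos and Junb lie higher in all 3 mutant libraries, and Bfsp2 lies lower in all 3.

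Over the genome, 272 of 12257 tested genes changed at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, 140 of them higher and 132 lower in the mutant libraries. Of these, 231 had a log2 fold change of at least 1 in size. None of the 272 had overlapping values between the groups; over all tested genes this held for 2788, or 22.7%, against 10% by chance. The genes with the largest increases included Slc35d3, Rprm, Ndnf, Ptgds, Zic5 and Tifa, each with a mean of 1 CPM or less in control libraries. Ndnf, which encodes a secreted neurotrophic factor, averaged 0.983 CPM ± 0.829 in control and 111.7 CPM ± 12.9 in mutant libraries (SD, n = 3). Ptgds, the gene of prostaglandin D synthase, had a log2 fold change of 6.39 ± 0.51, and Zic5, which encodes a zinc finger transcription factor, one of 6.30 ± 0.53 (SE). Slc35d3, Rprm and Tifa had log2 fold changes of 7.16, 6.98 and 5.84, and Nfam1 one of 4.08. Anxa2, the gene of the membrane-binding protein annexin A2, rose from 20.9 CPM ± 4.04 to 378.4 CPM ± 86.1 (SD, n = 3; edgeR adjusted p = 0.000199). Slc7a11, which encodes the cystine transporter subunit xCT, rose from 10.4 CPM ± 7.66 to 205.8 CPM ± 39.3 (SD, n = 3; edgeR adjusted p = 0.00843). The Tifa and Slc7a11 calls were lost without control library 2, where their log2 fold changes were 7.47 and 5.05.

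The genes with the largest decreases included Bfsp2, which encodes phakinin, a protein of the beaded filaments of fibre cells. Bfsp2 averaged 422.2 CPM ± 193.4 in control and 14.4 CPM ± 7.30 in mutant libraries (SD, n = 3), a log2 fold change of -4.88 ± 0.52 (SE; edgeR adjusted p = 0.00464). The called gene Tmem108, named after its values were seen, lay near Bfsp2 in gene order and also fell (log2 fold change -1.82). The embryos had a mixed strain background, and whether an inherited segment gave the Bfsp2 change was not tested. Wnt7a, which encodes a secreted Wnt ligand, had a log2 fold change of -4.13 ± 0.53 and Adam12, which encodes a membrane metalloprotease, one of -4.20 ± 0.32 (SE). The neurotrophin receptor gene Ngfr, the ephrin receptor gene Epha5 and the netrin-G gene Ntng2 had log2 fold changes of -4.48, -4.05 and -5.30. Pde1c and Poln had log2 fold changes of -4.32 and -3.98. Among these genes, the calls for Wnt7a (without mutant library 1), Epha5 and Pde1c (without control library 3 or mutant library 1 or 3), Ntng2 (without any of these 3 or control library 2) and Poln (without control library 2 or mutant library 1 or 3) were lost. Over the leave-out fits their log2 fold changes lay between -4.70 and -3.66, -4.46 and -3.48, -4.71 and -3.61, -5.74 and -4.73, and -4.35 and -3.56, in that order.

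A further 3 genes of the ranking had a single count in 1 of the groups. Raver2, which encodes an RNA-binding protein, had 2474 counts in control and 1 count in mutant libraries, a ratio of 2592 (95% exact interval 465 to 102428). Dynlt1b had 899 counts against 1, a ratio of 942 (95% exact interval 169 to 37246). H2-T10 had 913 counts in mutant against 1 count in control libraries, a ratio of 871 (95% exact interval 156 to 34454). These intervals cover counting error only. Dynlt1b and H2-T10 belong to families with near-identical members, so their gene assignment is uncertain.

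Genes that respond to FGF and ERK signalling moved in both directions. Of the 21 tested members of the list fixed for this response, 3 rose, 2 fell and 16 did not pass, and adjusted over the list alone 6 rose and 2 fell. Egr1, an immediate transcriptional target of ERK, rose from 10.3 CPM ± 3.61 to 163.3 CPM ± 65.9 (SD, n = 3), a log2 fold change of 3.98 ± 0.42 (SE; edgeR adjusted p = 0.00436). Fos rose by a log2 fold change of 3.43 ± 0.40 and Junb by 1.63 ± 0.27 (SE), both genes of AP-1 subunits. Spry2, which encodes a feedback inhibitor of receptor tyrosine kinases, fell from 19.3 CPM ± 0.995 to 7.97 CPM ± 1.23 (SD, n = 3; log2 fold change -1.28 ± 0.21 (SE); edgeR adjusted p = 0.0196). The ephrin receptor gene Epha2, named after its values were seen, had a log2 fold change of -0.87 ± 0.16 (SE). Epha2 lay in the longest run of called genes that neighboured one another in gene order. Feedback genes Dusp6, Spry1 and Spry4, also named after their values were seen, had log2 fold changes of -0.30 ± 0.34, 0.01 ± 0.20 and 0.06 ± 0.27 (SE) and did not pass; the sign of Spry1 turned with limma voom and, like those of Dusp6 and Spry4, when single libraries were left out. The list was called higher by camera (adjusted p = 0.0069), with a median log2 fold change of 0.13, and was not called with an estimated correlation (adjusted p = 0.526 with an estimated correlation). Its call was lost without control library 1 (camera adjusted p = 0.0537; median 0.18), and its median was 0.04 without control library 3. The immediate early list, which shares Egr1, Fos and Junb, had 3 of 14 members higher, 11 not past the threshold, and 5 higher and 1 lower adjusted over the list alone. It was called higher (camera adjusted p = 0.0119; adjusted p = 0.526 with an estimated correlation) although its median log2 fold change was -0.06. That median was 0.44 without control library 3, 0.09 without mutant library 2 and 0.20 with the filter of 5 CPM. Calls for Junb, Spry2 and Epha2 were lost without control library 2 or 3 or mutant library 1 or 3, with log2 fold changes between 1.52 and 1.72, -1.36 and -1.15, and -0.95 and -0.77 over the leave-out fits.

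In the list of FGF receptors and related genes, Fgfr1 fell. Of 9 tested members, 1 fell and 8 did not pass, and adjusted over the list alone 3 fell. Fgfr1 fell from 115.4 CPM ± 14.8 to 61.1 CPM ± 7.80 (SD, n = 3; log2 fold change -0.92 ± 0.15 (SE); edgeR adjusted p = 0.0204). Fgfr3 and Fgfrl1 had log2 fold changes of -1.45 ± 0.34 and -1.07 ± 0.25 without passing (SE; edgeR adjusted p = 0.0802 and 0.0824), and both passed with DESeq2, with limma voom and without mutant library 2, where they were -1.91 and -1.31. The list was called lower by camera (adjusted p = 0.00342) and was not called with an estimated correlation (adjusted p = 0.526 with an estimated correlation). It was also called by fry, which asks whether the genes of a list move one way on balance (adjusted p = 0.0267). The Fgfr1 call was lost without control library 2 or 3 or mutant library 1 or 3, where its log2 fold change lay between -1.02 and -0.81.

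Some genes of lens fibre differentiation fell. Of 30 tested fibre genes, 5 fell, 1 rose and 24 did not pass, and 26 had negative log2 fold changes; adjusted over the list alone, 7 fell and 1 rose. The members that fell were Bfsp2, Gata3, Grifin, Cdkn1c and Arvcf. Gata3, a transcription factor gene of early fibre cells, fell from 78.8 CPM ± 9.07 to 33.5 CPM ± 5.71 (SD, n = 3), and Grifin, which encodes a lens galectin relative, fell from 444.0 CPM ± 67.1 to 220.4 CPM ± 15.5 (SD, n = 3). Cdkn1c, which encodes a cyclin-dependent kinase inhibitor of cells leaving the cycle, fell from 2315 CPM ± 229 to 1029 CPM ± 145 (SD, n = 3; log2 fold change -1.17 ± 0.17 (SE); edgeR adjusted p = 0.0121). Arvcf (log2 fold change -1.10 ± 0.20) and Plekhb1, which rose by a log2 fold change of 2.41 ± 0.42 (SE), were named after their values were seen. The fibre transcription factor genes Prox1 and Maf, also named after their values were seen, had log2 fold changes of -0.44 ± 0.15 and -0.43 ± 0.19 and did not pass (SE). The list was called lower by camera (adjusted p = 2.0e-07), with a median log2 fold change of -0.68, and was not called with an estimated correlation (adjusted p = 0.526 with an estimated correlation) or by fry (adjusted p = 0.171). The median was -0.38 without control library 1, -1.08 without mutant library 2 and -0.27 with the crystallin share as a covariate, with the camera call kept. The median log2 CPM of its members was 8.62, 8.41 and 8.10 in control libraries 1, 2 and 3, and 7.42, 7.75 and 7.39 in mutant libraries 1, 2 and 3. The calls for Cdkn1c (without control library 2 or mutant library 1), Gata3 (without control library 2 or mutant library 3), and Grifin, Arvcf and Plekhb1 (without control library 2 or mutant library 1 or 3) were lost. Over the leave-out fits their log2 fold changes lay between -1.29 and -1.09, -1.34 and -1.11, -1.13 and -0.91, -1.22 and -0.85, and 2.06 and 2.95, in that order.

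Crystallins, the abundant structural proteins of the lens, took 37.6%, 30.2% and 21.8% of the counts in control libraries 1, 2 and 3, and 21.7%, 32.2% and 19.5% in mutant libraries 1, 2 and 3. The mean share of 29.9% ± 7.90 (SD, n = 3) in control and 24.5% ± 6.76 (SD, n = 3) in mutant libraries did not differ beyond the spread (difference -5.41 percentage points; exact two-sided permutation p = 0.4, with 0.1 the smallest this design allows). The difference in the share of counts from crystallin genes was -1.54 percentage points without control library 1, -9.43 without control library 3, -9.26 without mutant library 2 and -2.93 without mutant library 3. Of 8 alpha and beta crystallin genes, 1 fell and 7 did not pass, also adjusted over the list alone. This was Crybb2, with a log2 fold change of -2.19 ± 0.32 (SE; edgeR adjusted p = 0.0114), whose call was lost without control library 2 or 3 or mutant library 3 (log2 fold change between -2.43 and -2.05). None of 8 gamma crystallin genes passed over all genes in edgeR, where 1 fell adjusted over the list alone and 1 had an unadjusted p under 0.05, while DESeq2 and limma voom each called 1. Crygf averaged 1071 CPM ± 542 in control and 160.2 CPM ± 121 in mutant libraries (SD, n = 3; edgeR adjusted p = 0.0923), and passed without mutant library 2, at a log2 fold change of -3.50. Both lists were called lower by camera (adjusted p = 0.00079 and 0.0076), and neither was called with an estimated correlation (adjusted p = 0.526 and 0.657 with an estimated correlation). Without control library 1 the call of the gamma crystallin list was lost, at a median log2 fold change of -0.50 against -0.97, while without mutant library 2 or 3 the call was kept at medians of -1.57 and -0.63. Gamma crystallin genes are close copies of one another, so their values are uncertain one by one.

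**Figure D2:**
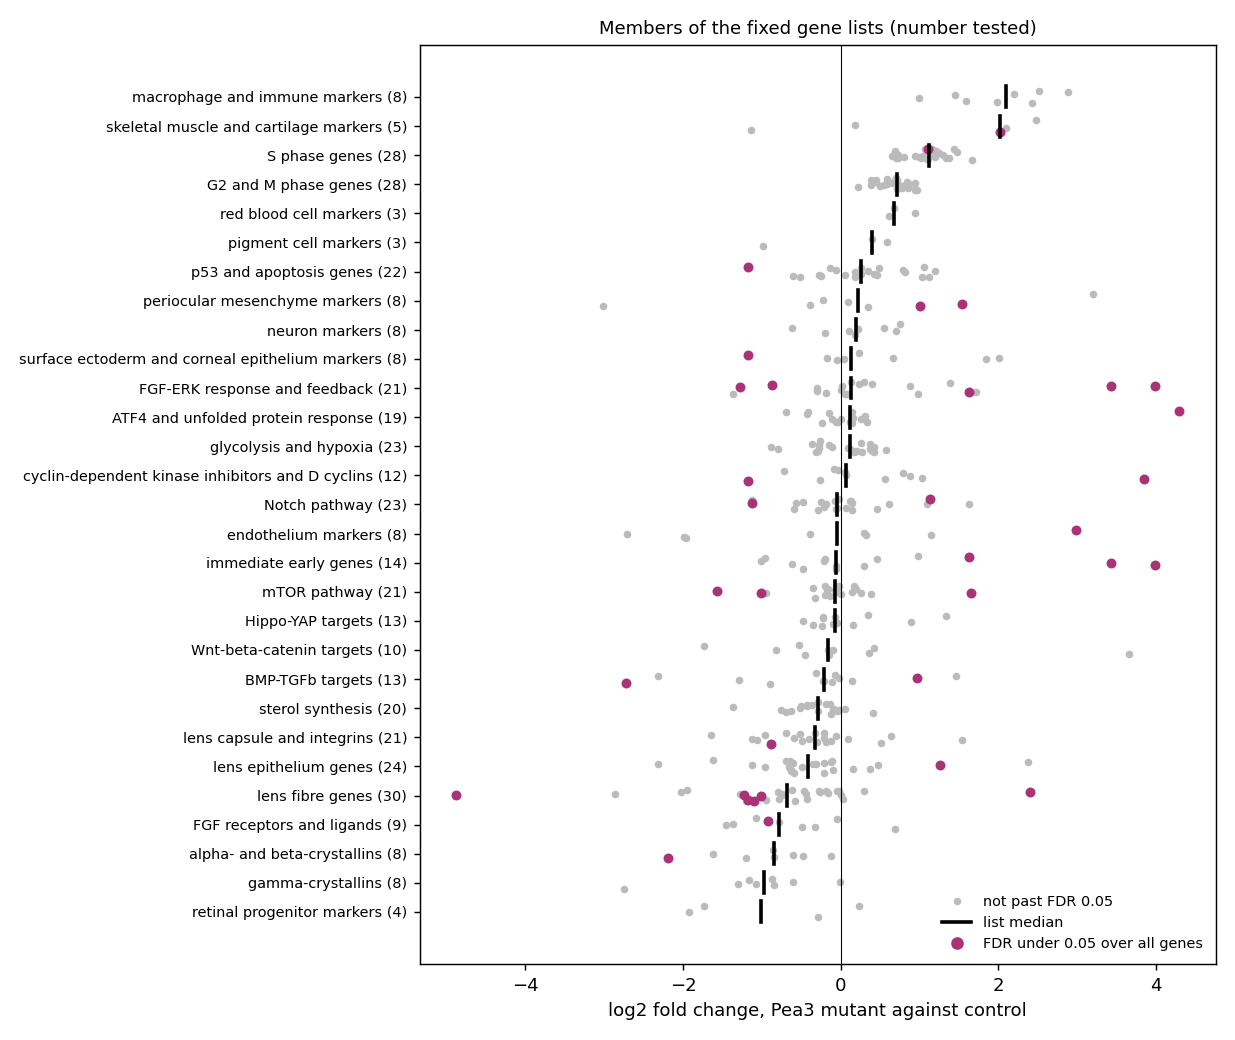
Log2 fold change of mutant against control libraries for each tested member of the fixed gene lists, ordered by list median, with the number of tested members in brackets. Grey points did not pass, purple points passed an adjusted p of 0.05 over all genes, and black bars are list medians; all 28 S phase genes lie above 0 and 26 of 30 fibre genes below 0.

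Of the tested genes of S phase and of G2 and M phase, Mcm2 alone passed in edgeR. All 28 tested S phase genes had positive log2 fold changes, with a median of 1.12, and 1 rose while 27 did not pass in edgeR; adjusted over the list alone, 2 rose. At an unadjusted p under 0.05 there were 19 S phase genes in edgeR, and DESeq2 and limma voom called 7 and 2. Mcm2, which encodes a subunit of the replicative helicase, rose from 170.4 CPM ± 36.4 to 366.5 CPM ± 19.96 (SD, n = 3; log2 fold change 1.10 ± 0.17 (SE); edgeR adjusted p = 0.0155). E2f1, a transcription factor gene of S phase entry, had a log2 fold change of 1.11 ± 0.25, and Rrm2, a ribonucleotide reductase gene, one of 1.66 ± 0.53, without passing (SE); without mutant library 2 E2f1 passed, at 1.24. All 28 tested G2 and M phase genes had positive log2 fold changes as well, with a median of 0.71, and none passed over all genes or adjusted over the list alone in edgeR, where 1 had an unadjusted p under 0.05; DESeq2 and limma voom called 0. Camera called both lists higher (adjusted p = 1.3e-11 and 3.8e-05), and neither was called with an estimated correlation (adjusted p = 0.604 and 0.657 with an estimated correlation) or by fry (adjusted p = 0.249 and 0.366). The G2 and M phase median was 0.40 without control library 1, 0.43 without mutant library 1 and 0.36 with the crystallin share as a covariate, with the camera call kept. Per library, the median log2 CPM of S phase genes was 3.97, 5.17 and 5.29 in controls 1, 2 and 3, and 6.15, 5.16 and 6.19 in mutants 1, 2 and 3. Mutant library 2, at the level of control libraries 2 and 3, also had the highest crystallin share of its group. The Mcm2 call was lost without control library 2 or mutant library 1 or 3 (log2 fold change between 0.94 and 1.21 over the leave-out fits).

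**Figure D3:**
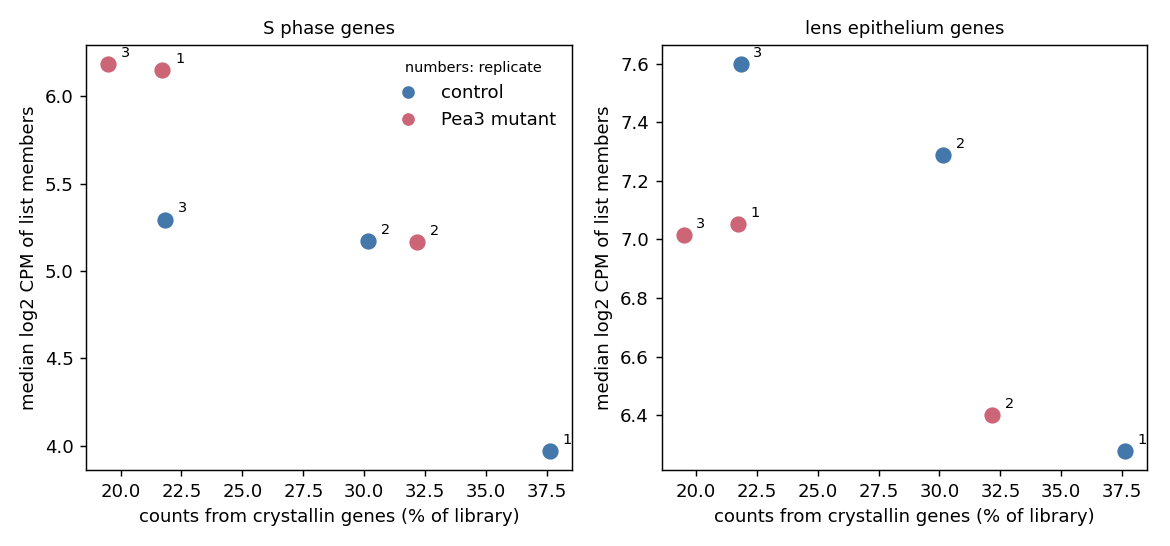
Median log2 CPM of S phase genes (left) and of lens epithelium genes (right) against the percent of counts from crystallin genes, with 1 point per library (control blue, mutant red, replicate number beside each point). Control library 1, with 37.6% crystallin counts, is lowest in both panels, and mutant library 2, with 32.2%, is lowest among the mutant libraries in both.

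Cyclin-dependent kinase inhibitors and D cyclins did not move as a group (12 tested; camera adjusted p = 0.505; 1 rose, 1 fell and 10 did not pass; adjusted over the list alone, 3 rose and 1 fell). Besides Cdkn1c, the inhibitor gene Cdkn2b rose, from 0.304 CPM ± 0.170 to 4.52 CPM ± 2.71 (SD, n = 3; edgeR adjusted p = 0.0363), a call lost without each library but mutant 2. Its log2 fold change lay between 3.53 and 4.33 over those fits.

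Among other signalling lists, single members changed while the lists as a whole did not pass camera. In the Notch pathway, 1 of 23 members fell and 1 rose, with 1 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.998, scored higher at a median log2 fold change of -0.04). Jag1 fell from 377.2 CPM ± 44.1 to 173.4 CPM ± 31.9 (SD, n = 3; log2 fold change -1.12 ± 0.17 (SE); edgeR adjusted p = 0.0126). Maml2, which encodes a Notch coactivator, rose by a log2 fold change of 1.13 ± 0.21 (SE). In the mTOR pathway, Mtor (-1.01 ± 0.13) and Tsc2 (-1.57 ± 0.30) fell and Rragd rose (log2 fold change 1.65 ± 0.23; SE), out of 21 members, with the same numbers adjusted over the list alone (camera adjusted p = 0.471). Mtor encodes the kinase itself, Tsc2 an upstream inhibitor and Rragd a GTPase that brings the complex to lysosomes. Mtor and Tsc2 each lay near another called gene in gene order. Of 13 BMP and TGF-beta genes, 1 fell and 1 rose, with 2 lower and 1 higher adjusted over the list alone. These were Id4, a target of BMP signalling (log2 fold change -2.72 ± 0.35), and the ligand gene Tgfb2 (0.97 ± 0.13; SE). Camera did not call this list (adjusted p = 0.182; adjusted p = 0.604 with an estimated correlation), while fry called it lower (adjusted p = 0.0057), as did camera with the crystallin share as a covariate (0.0355) and without both libraries of highest crystallin share (0.0248). None of 10 Wnt targets and none of 13 Hippo-YAP targets passed in edgeR, over all genes or adjusted over the list alone, and neither list was called (camera adjusted p = 0.720 and 0.998). At an unadjusted p under 0.05 there were 3 and 1, and DESeq2 and limma voom called 0 in each list; camera scored both lower, with negative medians and mean log2 fold changes of 0.05 and 0.07. The calls for Jag1 (without mutant library 1 or 3), Maml2 (without any library but mutant 2), Tsc2 and Rragd (without control library 2 or mutant library 1 or 3) and Id4 (without mutant library 3) were lost. Over the leave-out fits their log2 fold changes lay between -1.27 and -0.997, 1.02 and 1.23, -1.76 and -1.15, 1.49 and 1.95, and -3.19 and -2.47, in that order.

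Lens epithelium genes were not called as a list (24 tested; median log2 fold change -0.42; camera adjusted p = 0.0554), and 1 of them rose, also adjusted over the list alone, where 5 fell. The list was called lower with no filter (camera adjusted p = 0.0233), with the filter of 5 CPM (0.0205), and without control library 1 (0.00243), mutant library 1 (0.0460) or mutant library 2 (0.0408). It was also called lower with the crystallin share as a covariate (0.000194) and without both libraries of highest crystallin share (0.000125), alternatives chosen after seeing the data, but not with an estimated correlation (adjusted p = 0.632 with an estimated correlation) or by fry (adjusted p = 0.249). Without control library 3 its median was -0.25 (camera adjusted p = 0.261). DESeq2 and limma voom called 7 and 6 of its genes. The gene that rose in edgeR was Mab21l1, needed for lens formation, which rose from 171.8 CPM ± 16.4 to 412.4 CPM ± 19.9 (SD, n = 3; edgeR adjusted p = 0.00196). Pax6 and Foxe3, named after their values were seen, had log2 fold changes of 0.15 ± 0.18 and -0.66 ± 0.67 and did not pass (SE), and Pax6 turned to -0.01 without control library 1. Genes of the lens capsule and integrins were called lower by camera (21 tested; median log2 fold change -0.32; adjusted p = 0.0076; adjusted p = 0.526 with an estimated correlation). Of these, 1 fell, 20 did not pass, and 5 fell and 1 rose adjusted over the list alone, while DESeq2 and limma voom called 6 and 4. Nid1, which encodes the basement membrane protein nidogen, fell from 1337 CPM ± 259 to 723.1 CPM ± 17.3 (SD, n = 3; edgeR adjusted p = 0.0363), and its call was lost in every fit that left out a library except that without control library 1 (log2 fold change between -0.99 and -0.72). The capsule list itself lost its call without control library 3, at a median of -0.24, and kept it without control library 1, at -0.49. Sterol synthesis genes were called lower by camera with none of 20 passing in edgeR (median log2 fold change -0.29; adjusted p = 0.0098; adjusted p = 0.657 with an estimated correlation). Adjusted over the list alone, 1 gene fell. At an unadjusted p under 0.05 there were 6 in edgeR, and DESeq2 and limma voom each called 1. The sterol list lost its call without control library 1 or mutant library 1, at medians of -0.17 and -0.23, and with the crystallin share as a covariate (camera adjusted p = 0.227; median -0.21), and kept it without control library 3, at a median of -0.46.

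Stress and energy metabolism lists were not called by camera. Of 22 p53 and apoptosis genes, 1 fell, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.274). Perp, a p53 target gene of epithelial junctions, fell by a log2 fold change of -1.18 ± 0.19 (SE), a call lost without control library 2 or 3 or mutant library 1 or 3 (between -1.28 and -1.09). Of 19 genes of ATF4 and the unfolded protein response, Slc7a11 rose, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.505). None of 23 genes of glycolysis and hypoxia passed in edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.505), with 5 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma voom.

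Markers of other cell types were mostly at low levels. All 8 tested macrophage markers had positive log2 fold changes and none passed in edgeR, over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05, 0 called by DESeq2 and 1 by limma voom. The list was called higher (camera adjusted p = 0.0252; adjusted p = 0.657 with an estimated correlation). Its median log2 CPM was 2.14 and 2.15 in mutant libraries 1 and 3, which are those of highest S phase level, and -1.80 in mutant library 2, against 0.69, -0.72 and -1.56 in control libraries 1, 2 and 3. This call was lost without mutant library 1 or 3, at medians of 1.54 and 1.75, and with the crystallin share as a covariate (camera adjusted p = 0.230; median 1.98). Of 5 skeletal muscle and cartilage markers, Sox9, a transcription factor gene also expressed in progenitor cells of other tissues, rose by a log2 fold change of 2.02 ± 0.27 (SE), and 2 rose adjusted over the list alone. The list was called higher (camera adjusted p = 0.0223; adjusted p = 0.604 with an estimated correlation), and the call was lost without control library 1 or 3 or mutant library 1 or 3, with medians of 0.80, 0.87, 0.95 and -0.15. It was lost as well with no filter (camera adjusted p = 0.0851; median 0.17), with the filter of 5 CPM (0.162; median 0.18) and with the crystallin share as a covariate (0.0865; median -0.04 against 2.02). The Sox9 call was lost without mutant library 1 or 3 (log2 fold change between 1.86 and 2.20). Of 8 periocular mesenchyme markers, 2 rose, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0994). The collagen genes Col5a1 and Col5a2 rose by log2 fold changes of 1.001 ± 0.18 and 1.53 ± 0.27 (SE), calls lost without any library but mutant 2 (between 0.90 and 1.16, and between 1.32 and 1.69). Of 8 endothelium markers, Ramp2, which encodes a receptor activity modifying protein, rose by a log2 fold change of 2.99 ± 0.42 (SE), also adjusted over the list alone (camera adjusted p = 0.491, with a median log2 fold change of -0.05 for a list scored higher). The endothelium median lay between -1.24 (without control library 3) and 0.13 (without control library 1) over the leave-out fits. The Ramp2 call was lost without control library 2 or mutant library 3 (between 2.66 and 3.40). Of 8 surface ectoderm markers, Perp fell, also adjusted over the list alone (camera adjusted p = 0.826). None of the 4 retinal progenitor, 8 neuron, 3 red blood cell and 3 pigment cell markers passed in edgeR over all genes, and 1 retinal gene fell adjusted over the list alone. Of the retinal genes, 2 had an unadjusted p under 0.05 and DESeq2 and limma voom each called 1, while each of these counts was 0 for the other 3 lists. None of these lists was called (camera adjusted p = 0.281, 0.778, 0.491 and 0.998). The retinal list was called lower without control library 1 (0.0257), with the crystallin share as a covariate (0.0330) and without both libraries of highest crystallin share (0.00249). The periocular list was called higher with the filter of 5 CPM (0.00612), without control library 2 (0.0423) and without both libraries of highest crystallin share (0.0381), and the endothelium list with that filter (0.00768) and without both libraries (0.0176).

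The authors' deposited table listed 833 genes at an adjusted p under 0.05, of which 405 were higher and 428 lower in the mutant libraries. All 272 genes called by edgeR were among them with the same sign. In the authors' deposited table Etv1 had a log2 fold change of -1.09 (adjusted p = 0.00018) and Etv5 one of -0.91 (adjusted p = 0.00135). Etv4 had a log2 fold change of 0.60 in the authors' deposited table (adjusted p = 0.485).

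The count of 272 depended on single libraries: it was 92, 142, 98 and 91 without control library 2 or 3 or mutant library 1 or 3, and 479 without mutant library 2. With the crystallin share as a covariate, an alternative chosen after seeing the data, it was 776, and without the library of highest crystallin share in each group, chosen likewise, it was 1031, with 272 and 271 of the original genes among them.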

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

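The covariate and the removal of the library of highest crystallin share in each group were chosen only after the data were seen; the other alternatives here were not. The count of 272 called genes became 122 with a replicate block, 821 with DESeq2, 801 with limma voom, 89 at an adjusted p under 0.01 and 140 when tested against a log2 fold change of 0.5. It became 776 with the crystallin covariate and 1031 without both libraries of highest crystallin share. Leaving out 1 library gave from 91 (mutant library 3) to 479 (mutant library 2), with 223, 92 and 142 without control library 1, 2 and 3 and 98 without mutant library 1. All 272 genes kept their direction in each refit except the stricter filter, which tested 237 of them with the same direction. In the fits that left out libraries this was nearly fixed in advance, since none of the 272 had overlapping values between the groups. The share of higher calls, 51.5%, was 58.7% without control library 2, 60.2% without mutant library 1 and 60.4% without mutant library 3. It was below 50% without mutant library 2 (44.5%; 213 higher and 266 lower) and with the covariate (45.1%; 350 and 426), DESeq2 (48.1%), limma voom (48.6%), the stricter filter (49.0%) and without both libraries of highest crystallin share (49.4%). Etv1, Etv4 and Etv5 gave 1 gene called lower, 2 under normalization without crystallin genes, no filter, the stricter filter, DESeq2, voom and both added alternatives, and 0 with the replicate block and in the leave-out fits without control library 2 or 3 or mutant library 1 or 3 (range 0 to 1). Camera called 12 of 29 lists, or 0 with an estimated correlation, and fry called 2, the FGF receptor list and the BMP and TGF-beta list that camera had not called. The mean crystallin share kept its direction throughout. Over 77 named genes, 968 of 1148 values stayed on their side of the threshold, 139 lost and 31 gained the call (among them Etv5 7 times), and 10 reversed, all of genes without a call near 0. Over the fits without 1 library, Dusp6 ranged from -0.487 to 0.0152, Spry1 from -0.185 to 0.132, Spry4 from -0.0810 to 0.268 and Pax6 from -0.0138 to 0.287; voom turned Spry1 (-0.126), and the added alternatives turned Spry1 (-0.0784, both libraries left out) and Pax6 (-0.000456, covariate); over 12 lists, 139 of 179 stayed and 40 lost it. The block ended 24 and added 1 of these calls, and it ended that of the skeletal muscle and cartilage list (camera adjusted p = 0.0550; median 2.01). Deviations of same-numbered libraries from their group means correlated at -0.28, -0.15 and 0.22 for numbers 1, 2 and 3. No control library correlated best with its own number. These values give no clear sign of a pairing, but with 3 libraries per group they cannot exclude one. Leaving out a library lowers the sample number; otherwise the cause was not tested. The whole-series table was not run as another source because it is identical. Counts of 0 to 3 limit the size of the near-complete changes.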

Other observations

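The tests of neighbours among large and near-complete changes, of the whole fibre list, of Egr1, Fos and Junb, and of the longest run of neighbouring genes were chosen only after the results were seen, as were the genes named in the next 2 paragraphs and those named for the longest run. The tests of neighbouring genes and of the surroundings of Etv1, Etv4 and Etv5 were first written for near-complete changes and were assigned to all called genes after their results were seen.

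Further single genes rose beside Anxa2. S100a6 and S100a10, which encode S100 proteins that bind annexins, had log2 fold changes of 2.44 ± 0.20 and 2.37 ± 0.38 (SE). These S100 genes lay near each other in gene order. Ahnak, which encodes a scaffold that binds this complex, had one of 2.54 ± 0.38, and Tagln2, which encodes an actin-binding protein, one of 3.06 ± 0.39 (SE). The tubulin gene Tubb6 averaged 317.8 CPM ± 72.1 in control and 763.6 CPM ± 67.4 in mutant libraries (SD, n = 3). Calls were lost for S100a10 without any library but mutant 2, Ahnak without control library 2 or mutant library 1 or 3, and Tubb6 without control library 2 or mutant library 3, with log2 fold changes between 2.02 and 2.70, 2.27 and 2.80, and 1.12 and 1.45 over the leave-out fits. Nab1 and Nab2, which encode corepressors that bind Egr1, had log2 fold changes of 2.90 ± 0.27 and 3.76 ± 0.34 (SE).

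Among genes that fell, Pmp22, a gene of a tetraspan membrane protein, went from 666.7 CPM ± 59.5 to 91.6 CPM ± 19.7 (SD, n = 3). Ptgfr, the prostaglandin F receptor gene, fell by a log2 fold change of -2.70 ± 0.28, and Col13a1, a transmembrane collagen gene, by -3.66 ± 0.32 (SE). Gfra2 and Lingo3, receptor and adhesion genes best known from neurons, fell with log2 fold changes of -4.09 ± 0.51 and -3.20 ± 0.24 (SE). Cyp26a1, which encodes an enzyme that degrades retinoic acid, had a log2 fold change of -2.34 ± 0.38, and the glutathione transferase gene Gstm1 one of -2.25 ± 0.29 (SE). The Cyp26a1 call was lost without control library 2 or 3 or mutant library 1 or 3 (between -2.62 and -1.99 over the leave-out fits) and the Gstm1 call without control library 2 or mutant library 1 (-2.21 and -2.30). These genes passed the threshold over all genes and were not tested as groups.

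A split of the 6 libraries by group called 272 genes, and the highest of the other 9 splits called 0. Each of those 9 splits put libraries of both groups on both sides, so a difference between the groups adds to the spread within sides. Their 0 calls therefore do not show how many genes would be called by chance. Only 1 of 10 splits was as large, the real one, and 10 splits are too few for a share under 0.05.

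Several called genes were nearly absent from 1 group, among them Raver2, H2-T10 and Dynlt1b, and the embryos had a mixed strain background, so chromosome segments inherited from different strains may differ between the groups. Of the called genes, 77 had another called gene within 5 tested genes in gene order, against a median of 54 in random draws matched on expression (permutation p = 0.0074). The longest run held 7 genes, among them Capzb, Padi4 and Epha2 (random median 3). In gene order, the only called genes between the longest run and that of Agtrap, Fbxo44 and Mtor were Gm13152 and Gm13157. All of these fell, and in the longest run all fell but Igsf21 and Necap2. The genes named for these runs were chosen after the results were seen. Other genes named here also lay in runs of 2 or 3 called genes. Among them were Tsc2, Perp, Slc35d3, Bfsp2, Wnt7a, Id4, Zic5, Raver2, Dynlt1b, Crybb2, Plekhb1, Col5a1, Ramp2, Gfra2, S100a6 and S100a10. Whether strain segments account for these calls was not tested gene by gene. Of 70 called genes with an absolute log2 fold change of at least 3, 18 had another within 20 genes (random median 14; permutation p = 0.219), while of the 18 called genes with at most 3 counts in 1 group 6 did (random median 0; permutation p = 0.0091). Among the 100 tested genes on each side of Etv1, Etv4 and Etv5, 14 genes were called (random median 12, permutation p = 0.331). Of these, 3 lay around Etv1, 7 around Etv4, with Ramp2 and Sox9 among them, and 4 around Etv5, with Arvcf among them. Segments around the targeted loci cannot be told apart from chance with so few genes. Co-regulated neighbours would also give runs, and strains were not given per library, so strain segments stay a candidate explanation for part of the called genes.

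The higher S phase level may come from pieces with less fibre material or from the differentiation state of the mutant lens. With the crystallin share as a covariate, the median log2 fold change of S phase genes was 0.67 against 1.12. This drop lies between the bounds set for and against less fibre material, so the explanations cannot be told apart for these genes. In the same fit 4 of them were called, all higher, against 1 without the covariate, while calls over all genes went from 272 to 776. The list stayed called higher by camera at the preset correlation (adjusted p = 5.9e-09). The S phase median stayed above 0, the outcome set for a difference in differentiation state, with 0.45 the lowest value when 1 library was also left out. A covariate that captures fibre material only in part would leave the same, so this does not tell the explanations apart. For the 5 called fibre genes that were lower, the median was -1.15 with the covariate against -1.17 without it, which met the bound set against less fibre material. These 5 were picked by their calls, which favour genes that vary little between libraries of a group. The covariate could therefore change them little, so this does not decide the cause. Over all 30 fibre genes the median went from -0.68 to -0.27, as less fibre material would give. In that fit 8 fibre genes were called lower and 1 higher, against 5 and 1 without the covariate. Camera still called the list lower at the preset correlation (adjusted p = 3.4e-08). Without the covariate its estimated correlation was 0.28, and camera did not call it with that estimate (adjusted p = 0.526). The cause stays open for the list, and crystallins are fibre genes themselves, so the covariate also removes differences in differentiation state.

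Egr1, Fos and Junb are also induced by handling of tissue. The 14 tested immediate early genes had a median log2 fold change of -0.058, with 6 positive and 8 negative, and one of 0.44 without control library 3 and 0.20 with the filter of 5 CPM; these values include the 3 genes to be explained. The other 11 had a median of -0.21, with 3 positive and 8 negative (from -1.01 to 0.98). Of these, Ier2 alone reached 0.81, which is 50% of the Junb change, at a log2 fold change of 0.98 ± 0.25 (SE) without passing. Arc, an immediate early gene outside the fixed list, was called higher and was named after its values were seen. It had 77 counts in mutant and 1 count in control libraries, a ratio of 73.5 (95% exact interval 12.8 to 2940). Because these 11 are what remains once the called genes are taken out, they do not exclude handling, which stays open, and whether loss of Pea3 factors raises Egr1, Fos and Junb was not tested. A single library did not carry the pattern, since the lowest log2 fold change of the 3 genes was 1.52 when 1 library was left out.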
